A study of Mus musculus with 16 samples.

How the data were processed

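Single-cell RNA sequencing was done on cells of the stromal vascular fraction of mouse brown adipose tissue, the cells left after enzymatic digestion once the floating fat cells are taken off. Per the labels' protocols, interscapular tissue of C57BL6J mice was digested with collagenase and dispase, the adipocyte layer and the red blood cells were removed, dead cells were depleted on a column kit, and libraries were made with the Chromium Single Cell 3' v3 kit. Alignment and counting used STAR and Cell Ranger 3.0.1 against mm10, per the submitters' processing notes; their filters on cells, their integration and their clustering settings are not given in the sources used here.

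The data analysed were per-cell annotations, with 109723 cells of 16 libraries in one table and 24352 of the same cells, from 15 libraries, in another. UMI counts and counts of detected genes per cell were deposited by the authors as whole numbers without normalisation. The mitochondrial fraction per cell was deposited by the authors on a scale from 0 to 1 and is given here in percent. The ratio of log10 genes to log10 UMIs per cell was also deposited by the authors and was not used here. S and G2M phase scores and the phase call made from them were deposited by the authors; they differ between the tables, with equal calls for 56.5% of the 24352 cells, so scores and calls of each table were compared only within it. Cluster numbers were deposited by the authors at several resolutions of a graph clustering. The smaller table also gives cluster names, which were used as they stand, and a cluster without a name stayed a number. Gene values were not analysed here, so no cluster name was checked against marker genes, doublets were not called, and cells were not thinned to a fixed number of UMIs.

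From the tables, the share of each library's cells in each cluster was computed, and the library was the unit of replication. The first family of tests took the 61 clusters of all cells at resolution 1.8. The second took the 28 named clusters, at resolution 1.2, as shares of the named cells. Clusters with a mean of at least 10 cells per library were tested, which left 55 of the 61 and 27 of the 28. Each share, with 0.5 cells added to the cluster and to the rest, was put on the log2 odds scale and fitted with limma 3.58.1 in R 4.3.3, with 4 groups in one fit and 6 contrasts. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05, and all tests were two-sided. Differences are given as log2 odds ratios ± standard error. After the names had been seen, the named clusters were also summed into 9 classes by the start of their name and tested in the same way. A cluster of all cells was called dominated by a class when at least 50% of its cells, leaving aside 2-day cold replicate 1, carried a name and that class was the most common name among them.

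Depth, quality and the share of cells called S or G2M were compared per pair of groups with exact permutation tests on the library values. With 4 libraries against 4 there are 70 assignments and the smallest possible p is 0.0286. Phase calls were also compared within each cluster that held at least 20 cells in every library, with limma on the log2 odds of the share called S or G2M. The clusters to be named were fixed in advance: in each contrast those past the threshold (with more than 10, the 5 largest rises and the 5 largest falls), those past the test over all groups, and all clusters named as adipocyte, progenitor, smooth muscle, pericyte, endothelial or Schwann cells; outside 7-day cold against thermoneutral housing the last set is summarised by class. The groups, the tests, this rule and most alternatives were fixed before the data were examined.

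The limma step was tested on cell numbers simulated for the libraries of all 4 groups, with the fitted spread between libraries. Known changes were put into 7-day cold and read in its comparison with thermoneutral housing. Libraries were drawn independently, so the structure by replicate number described below was not simulated, and the rates hold for such libraries. Clusters were drawn independently as well, so a changed cluster did not move the shares of the others, as it does in the data. False calls that arise in that way are not in these rates. Over 55 clusters, 5%, 28.3% and 85% of the clusters changed 2-fold, 4-fold and 16-fold in odds were recovered, and 5.33% of the calls were false. Over 27 named clusters, 10%, 55% and 85% were recovered, and 5.26% of the calls were false.

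Libraries held 1473 to 10005 cells, and shares of single libraries are given with 95% Wilson intervals; a share of 0 is given with the limit that 3 cells would set. These intervals and limits cover counting error alone. No pair of libraries of one group agreed within sampling noise: the lowest chi-square per degree of freedom over cluster numbers was 14.5, and at most 39 cell barcodes were shared. The labels number the replicates 1 to 4 in each group, and do not say whether they are separate animals, so the p-values measure the spread between these libraries, which may be technical. Alternatives were another scale for the shares, edgeR 4.0.16 on the cell numbers with and without TMM scaling, centred log ratios, other denominators, filters on clusters and on cells, a coarser clustering, other sets of libraries, each library left out, and replicate numbers as a block, or replicates 1 and 2 against 3 and 4 as a covariate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables, exact tests and plots.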

Results

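Cells of the stromal vascular fraction of mouse brown adipose tissue, the heat-producing fat of the upper back, were profiled after housing at 4 conditions, to describe how the cell composition of the tissue changes with cold. Thermoneutral housing at 30 °C, room temperature at 22 °C, 2 days at 5 °C and 7 days at 5 °C had 4 libraries each, 109723 cells in all. The authors placed these cells in 61 clusters and gave names to 28 clusters of 24352 of the cells. The names begin with VSM (read as vascular smooth muscle, the contractile cells of vessel walls), VSM-AP, AP, EC, ECAP, Lymph_EC, Pericyte, Schwann and Adipo; of these, VSM is in the series title and the rest are kept as labels. A further 77.8% of the cells carried no name. Replicate 1 of 2-day cold had no named cells, so values over named cells have 3 libraries for 2-day cold and 4 for each other condition.

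Libraries held 1473 to 10005 cells, with a median of 1978.5 to 9819 UMIs per cell. In 5 libraries the cell number lay between 10000 and 10005, and the lowest UMI count in these was 1031 to 1921, against 800 to 809 in the others. Cells per library averaged 5220.5 ± 3308 (SD, n = 4) in 7-day cold and 9726.5 ± 399 (n = 4) in 2-day cold, a difference of -4506 with an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.686 over 24 tests. The other 23 comparisons of cell number, UMIs, genes and mitochondrial share between conditions had exact p-values of 0.0857 or more. Replicate 1 of 2-day cold stood apart, with a median of 9819 UMIs and a median mitochondrial share of 29.1%, against 2.47% to 3.70% in the other 2-day libraries. Depth also differed by replicate number: the median UMI count was 5461 ± 2124 (SD, n = 8) in replicates 1 and 2 and 2788 ± 514 (n = 8) in replicates 3 and 4, with the first higher in all 4 conditions (exact permutation within conditions, 1296 assignments, p = 0.00154). Median genes per cell were 1668 ± 307 and 1083 ± 151 (exact p = 0.00154), and the share of cells called S or G2M was 45.9% ± 11.6 and 60.8% ± 8.76 (exact p = 0.0216). Changes are therefore also given within replicates 1 and 2 and within replicates 3 and 4.

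**Figure D1:**
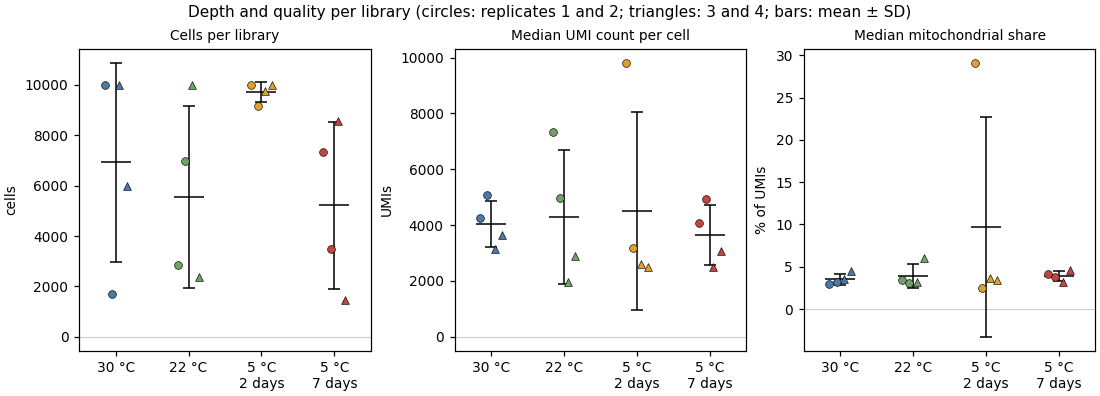
Cells per library, median UMI count per cell and median mitochondrial share (percent of UMIs) for each library, by housing condition; circles are replicates 1 and 2, triangles replicates 3 and 4, and bars the mean ± SD of 4 libraries. Replicate 1 of 2-day cold lies at 9819 UMIs and 29.1% mitochondrial UMIs, apart from the other 2-day libraries.

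Room temperature was first compared with thermoneutral housing, at which the tissue is not called on to make heat. VSM cells were 54.3% ± 11 (SD, n = 4) of named cells at room temperature and 58.5% ± 13.6 (n = 4) at thermoneutrality. ECAP cells were 6.42% ± 5.83 and 14.9% ± 9.24, Schwann cells, the glia of peripheral nerves, 4.75% ± 2.91 and 2.00% ± 1.55, and Adipo cells 3.15% ± 5.93 and 0.0802% ± 0.0952. The Adipo mean at room temperature came from replicate 4, with 12% (95% Wilson interval 9.07 to 15.8), while the other libraries held 0.0650% to 0.366%. With limma, 0 of 9 classes, 0 of 27 named clusters and 0 of 55 clusters of all cells passed; 0, 1 and 1 had an unadjusted p below 0.05, and edgeR called 0 in each of the 3 families. The adipocyte layer and dead cells were removed before sequencing, a step that can set the Adipo shares. The log2 odds ratio for Adipo was -0.89 within replicates 1 and 2 and 6.46 within replicates 3 and 4, and for VSM 0.71 and -1.24, so neither direction held in both.

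After 2 days at 5 °C, Adipo cells rose to 12.7% ± 10.7 (SD, n = 3) of named cells from 0.0802% ± 0.0952 (n = 4) at thermoneutrality. The 3 cold libraries held 1.83% to 23.1%, each above every thermoneutral library. Both Adipo clusters rose: Adipo_16 was 8.67% ± 6.31 against 0.0535% ± 0.0901, and Adipo_24 4.08% ± 5.04 against 0.0267% ± 0.0535. VSM_21, 1 of the 10 VSM clusters, also rose, to 1.70% ± 0.402 from 0.605% ± 0.0609. Of the classes that did not pass, VSM was 38.8% ± 5.49 against 58.5% ± 13.6 (adjusted p = 0.0824), AP 14.8% ± 4.91 against 6.78% ± 5.49 (adjusted p = 0.0760) and Schwann 7.11% ± 5.44 against 2.00% ± 1.55 (adjusted p = 0.0706). All 4 AP clusters had estimates above 0 and 7 of the 10 VSM clusters below 0, none of these past the threshold. In limma the log2 odds ratio was 7.02 ± 1.48 for the Adipo class (adjusted p = 0.00242), 6.98 ± 1.59 for Adipo_16 (adjusted p = 0.0146), 5.26 ± 1.41 for Adipo_24 (adjusted p = 0.0285) and 1.41 ± 0.41 for VSM_21 (adjusted p = 0.0366). Within replicates 1 and 2 and within 3 and 4, the Adipo class gave 6.23 and 8.15 and VSM_21 gave 1.06 and 1.63. The first value of each rests on 2-day replicate 2 alone, since 2-day replicate 1 had no named cells. Thermoneutral libraries held 6 Adipo cells in all and 2 of them held 0 (limits of 0.216% and 0.117%), so the size of the Adipo ratios depends on the 0.5 cells added. Adipo cells had a median mitochondrial share of 33.5% and 84.7% of them lay at 20% or more. Without such cells, a filter added after seeing the data, Adipo had too few cells to be tested, no named cluster passed in limma, and AP and Schwann passed. With Adipo tested all the same, its estimate was 3.70 ± 1.50 and its call ended (limma, adjusted p = 0.0796). AP and Schwann then did not pass (limma, adjusted p = 0.0670 for both). The 1 called class was higher, and with centred log ratios 1 was higher and 3 (VSM, ECAP and VSM-AP) were lower. The count of 1 was 3 without thermoneutral replicate 1 and 2 without thermoneutral replicate 2, room-temperature replicate 1 or 2-day replicate 4. Among named clusters the count of 3 was 0 without thermoneutral replicate 4 or without 2-day replicate 2 or 4, 1 without thermoneutral replicate 3 and 7 without thermoneutral replicate 1. VSM_21 lost its call in 19 of 29 settings, Adipo_16 in 4 of 28 and Adipo_24 in 8 of 28, the arcsine scale and centred log ratios among them.

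Among all cells, with 4 libraries of 2-day cold, 4 of 55 clusters rose and 1 fell against thermoneutrality. Clusters 11 and 45, in which 99.5% and 99.3% of the named cells were Adipo, were 7.34% ± 12.2 (SD, n = 4) and 0.858% ± 0.860 of cells in 2-day cold, and 0.00250% ± 0.00500 each at thermoneutrality. Replicate 1 of 2-day cold held 25.6% of its cells in cluster 11, and the other 2-day libraries 0.195% to 1.83%. Clusters 23 and 36, which hold no named cells, rose to 3.49% ± 4.03 from 0.0108% ± 0.0157 and to 1.54% ± 0.728 from 0.0362% ± 0.0210. Of their cells 94.7% and 89.9% were called S, and replicate 3 of 2-day cold held 63.0% of the cells of cluster 23. Cluster 46, also without named cells and with mean S and G2M scores of 0.354 and 0.509, fell to 0.145% ± 0.0535 from 0.502% ± 0.213. The log2 odds ratios in limma were 7.56 ± 1.50 for cluster 11 (adjusted p = 0.00220), 6.55 ± 1.10 for cluster 23 (adjusted p = 0.000525), 5.10 ± 0.73 for cluster 36 (adjusted p = 0.000172), 5.30 ± 1.15 for cluster 45 (adjusted p = 0.00405) and -1.75 ± 0.50 for cluster 46 (adjusted p = 0.0342). All 5 kept their direction within replicates 1 and 2 and within replicates 3 and 4, with -2.13 and -1.36 for cluster 46. The call of cluster 46 was lost in 14 of 30 settings, among them without thermoneutral replicate 1, 2 or 3 and without 2-day replicate 1, 3 or 4. The count of 5 was 3 among cells at or above the median UMI count. There clusters 23 and 36 had too few cells to be tested, and cluster 20 was added as higher (5.88 ± 1.67, limma, adjusted p = 0.0402). The count was 2 among cells under 20% mitochondrial UMIs.

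**Figure D2:**
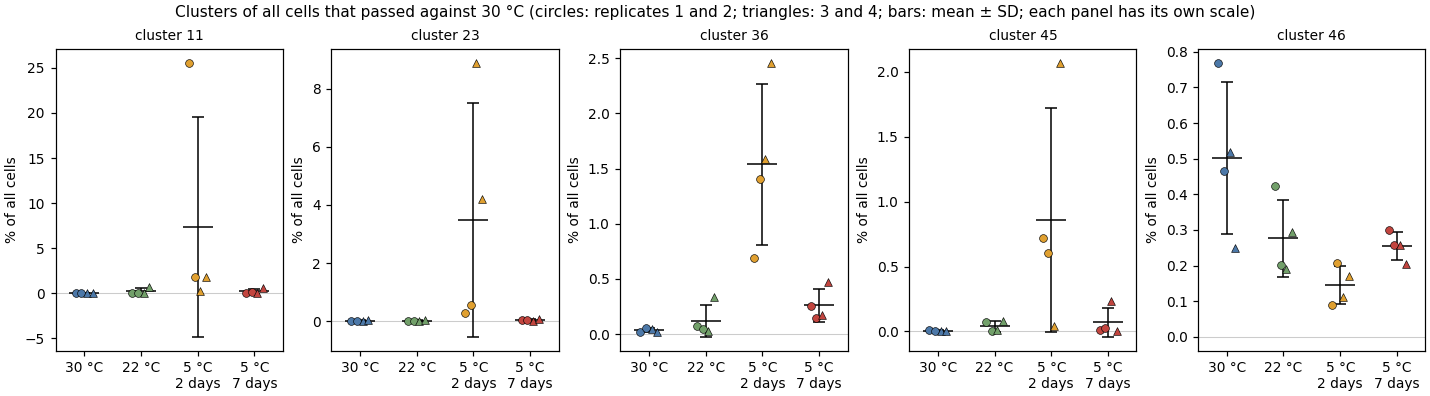
Share of each library's cells (percent) in the 5 clusters of all cells that passed in 2-day cold against thermoneutral housing, by condition; circles are replicates 1 and 2, triangles replicates 3 and 4, bars the mean ± SD of 4 libraries, and each panel has its own scale. Replicate 1 of 2-day cold lies at 25.6% in cluster 11, while all 4 libraries of 2-day cold lie above the thermoneutral ones in clusters 23 and 36.

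After 7 days at 5 °C, VSM cells fell to 30.5% ± 6.92 (SD, n = 4) of named cells from 58.5% ± 13.6 (n = 4) at thermoneutrality, and every cold library lay below every thermoneutral one. Schwann cells rose to 12.3% ± 1.24 from 2.00% ± 1.55, AP cells to 16.1% ± 3.99 from 6.78% ± 5.49, Lymph_EC cells to 3.5% ± 1.49 from 0.776% ± 0.184, Adipo cells to 1.95% ± 1.09 from 0.0802% ± 0.0952, and Pericyte cells, the mural cells of small vessels, to 10.1% ± 8.77 from 1.78% ± 1.35. Pericyte shares of the cold libraries were 18.5% and 16.8% in replicates 1 and 2, but 3.11% and 1.91% in replicates 3 and 4. The latter lay inside the range of the thermoneutral libraries, 0.352% to 3.42%. EC (14.9% ± 3.68 against 9.94% ± 3.61), ECAP (6.49% ± 6.76 against 14.9% ± 9.24) and VSM-AP (4.16% ± 1.55 against 5.29% ± 2.23) did not pass, and the EC estimate changed sign with centred log ratios. Without cells of 20% or more mitochondrial UMIs, which were 66.5% of VSM-AP cells, the VSM-AP estimate moved from -0.32 ± 0.46 to -1.90 ± 0.52 and passed (limma, adjusted p = 0.00376). Adipo, tested there without the minimum of cells, moved to 2.93 ± 1.39 and did not pass (limma, adjusted p = 0.0681). VSM-AP also passed as lower with centred log ratios. With VSM left out of the denominator ECAP passed as lower, at -2.77 ± 0.93 (limma, adjusted p = 0.0241), as it did with centred log ratios and with libraries of 3000 cells or more. The log2 odds ratios in limma were -1.72 ± 0.48 for VSM (adjusted p = 0.00847), 2.99 ± 0.63 for Schwann (adjusted p = 0.00237), 1.70 ± 0.57 for AP (adjusted p = 0.0148), 2.08 ± 0.58 for Lymph_EC (adjusted p = 0.00847), 4.62 ± 1.37 for Adipo (adjusted p = 0.00969) and 2.44 ± 0.83 for Pericyte (adjusted p = 0.0148). Within replicates 1 and 2 and within 3 and 4 the estimates were -1.32 and -2.13 for VSM, 2.31 and 3.68 for Schwann, and 0.85 and 2.55 for AP. Pericyte gave 2.88 and 2.00, Adipo gave 2.42 and 6.81, and Lymph_EC was higher within both pairs. The Adipo class held 49 cells in 7-day cold, 8 to 15 per library. At thermoneutrality it held 6, with 0 in replicates 3 and 4, so the size of its ratio depends on the 0.5 cells added. Of the 6 calls 5 were higher and 1 lower; with TMM scaling 2 were higher and 1 lower, and with centred log ratios 2 higher and 3 lower. As shares of all cells, a denominator added after seeing the data, 0 classes passed in limma (3 at an unadjusted p below 0.05), with -1.94 ± 0.76 for VSM and an adjusted p of 0.0595. With replicates 1 and 2 against 3 and 4 as a covariate on that denominator, 4 passed. Leaving out thermoneutral replicate 4 or 7-day replicate 2 ended the calls of AP and Pericyte, and leaving out 7-day replicate 1 that of Pericyte.

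**Figure D3:**
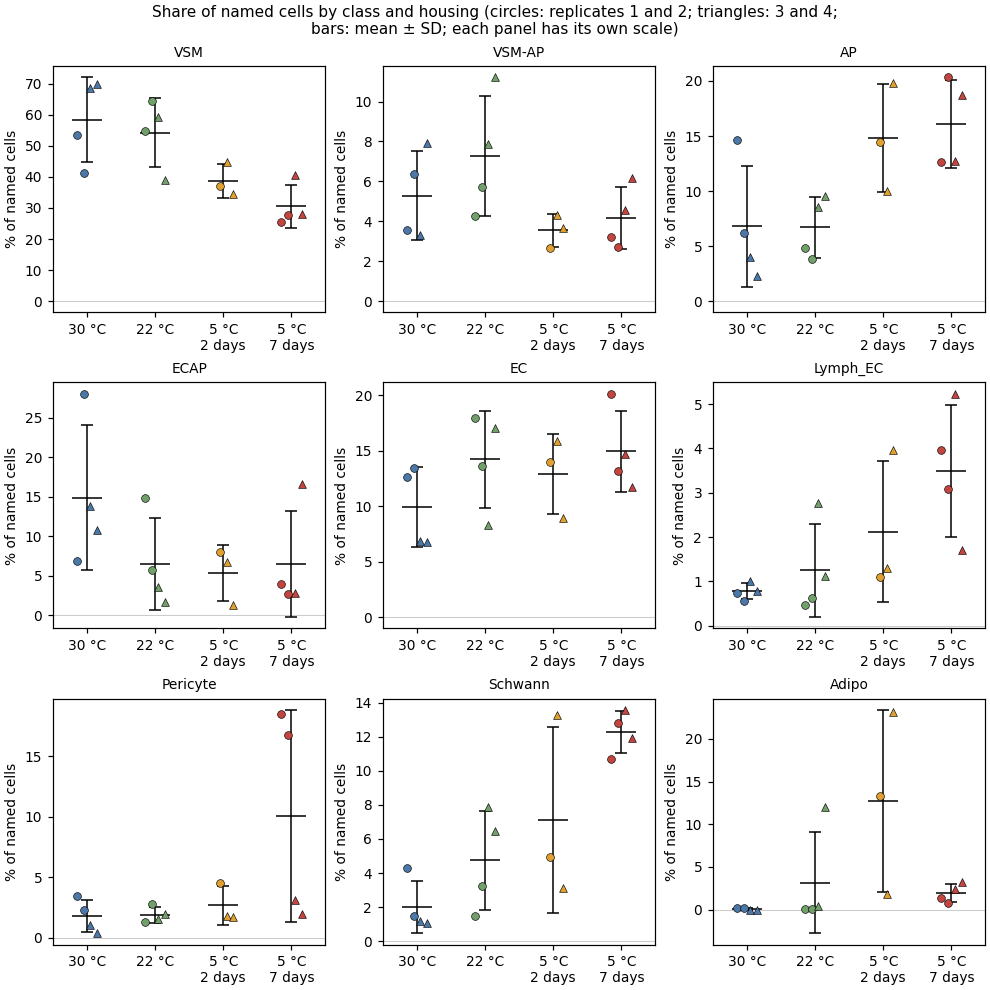
Share of each library's named cells (percent) in the 9 classes of named clusters, by housing condition; circles are replicates 1 and 2, triangles replicates 3 and 4, and bars the mean ± SD of 4 libraries (3 for 2-day cold), each panel on its own scale. VSM averaged 58.5% at thermoneutrality and 30.5% in 7-day cold, while Schwann averaged 2.00% and 12.3%.

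The VSM clusters did not move together in 7-day cold. VSM_2 fell to 3.38% ± 0.396 (SD, n = 4) from 10.6% ± 2.70 (n = 4), while VSM_21 rose to 3.62% ± 1.32 from 0.605% ± 0.0609. The other 8 VSM clusters did not pass: VSM_0 was 5.38% against 10.8%, VSM_1 3.09% against 14.2%, VSM_3 5.68% against 7.97%, VSM_5 2.92% against 6.14%, VSM_7 2.63% against 4.35%, VSM_20 1.07% against 1.46%, VSM_22 2.21% against 1.30% and VSM_27 0.524% against 1.09%. Both Schwann clusters rose, Schwann_14 to 9.07% ± 2.54 from 1.47% ± 0.825 and Schwann_18 to 3.19% ± 2.18 from 0.538% ± 0.730. Of the 4 AP clusters AP_8 rose to 5.93% ± 3.19 from 1.99% ± 1.82 and AP_26 to 2.78% ± 0.811 from 0.518% ± 0.306, while AP_9 (5.93% against 3.68%) and AP_25 (1.48% against 0.588%, adjusted p = 0.0501) did not pass. EC_10 rose to 7.20% ± 2.86 from 2.02% ± 0.337, and the other tested EC clusters did not pass, with EC_11 at 1.61% against 3.59%, EC_15 at 4.45% against 2.15%, EC_23 at 0.895% against 1.55% and EC_28 at 0.667% against 0.592%. EC_32, with too few cells for the main tests, was 0.118% against 0.0468%. Adipo_16 rose to 1.31% ± 1.15 from 0.0535% ± 0.0901, and Adipo_24 (0.637% against 0.0267%, adjusted p = 0.0537) did not pass. Pericyte_12, Lymph_EC_19, ECAP_4 and VSM-AP_6 are the sole clusters of their classes, with the values given for those.

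In limma 9 of 27 named clusters were higher and 1 lower. The log2 odds ratios were 2.49 ± 0.38 for VSM_21 (adjusted p = 0.000266), 2.81 ± 0.46 for Schwann_14 (adjusted p = 0.000266), 1.83 ± 0.48 for EC_10 (adjusted p = 0.0163), 2.60 ± 0.72 for AP_26 (adjusted p = 0.0163) and -1.70 ± 0.53 for VSM_2 (adjusted p = 0.0256), and the calls of AP_8, Adipo_16, Lymph_EC_19, Pericyte_12 and Schwann_18 had adjusted p-values from 0.0163 to 0.0290. Within replicates 1 and 2 and within 3 and 4, VSM_21 gave 2.76 and 2.23, Schwann_14 gave 2.44 and 3.18, and VSM_2 gave -1.22 and -2.19. With replicates 1 and 2 against 3 and 4 as a covariate 17 clusters passed, the added ones being AP_25, EC_15 and Adipo_24 as higher and VSM_0, VSM_1, VSM_27 and EC_11 as lower. With TMM scaling 6 clusters were higher and 4 lower, and with centred log ratios 4 higher and 6 lower. The count of 10 was 5 without thermoneutral replicate 3 and 4 without thermoneutral replicate 4. Single calls were lost without 7-day replicate 1 (Adipo_16, Pericyte_12), 2 (AP_8, Pericyte_12, Schwann_18) or 4 (Adipo_16, Schwann_18). Over the 55 clusters of all cells, limma called 0 and edgeR 0, with 8 at an unadjusted p below 0.05 in limma; the count was 1 without room-temperature replicate 4. It was 3 among cells under 20% mitochondrial UMIs (clusters 4 and 24 lower, 36 higher).

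**Figure D4:**
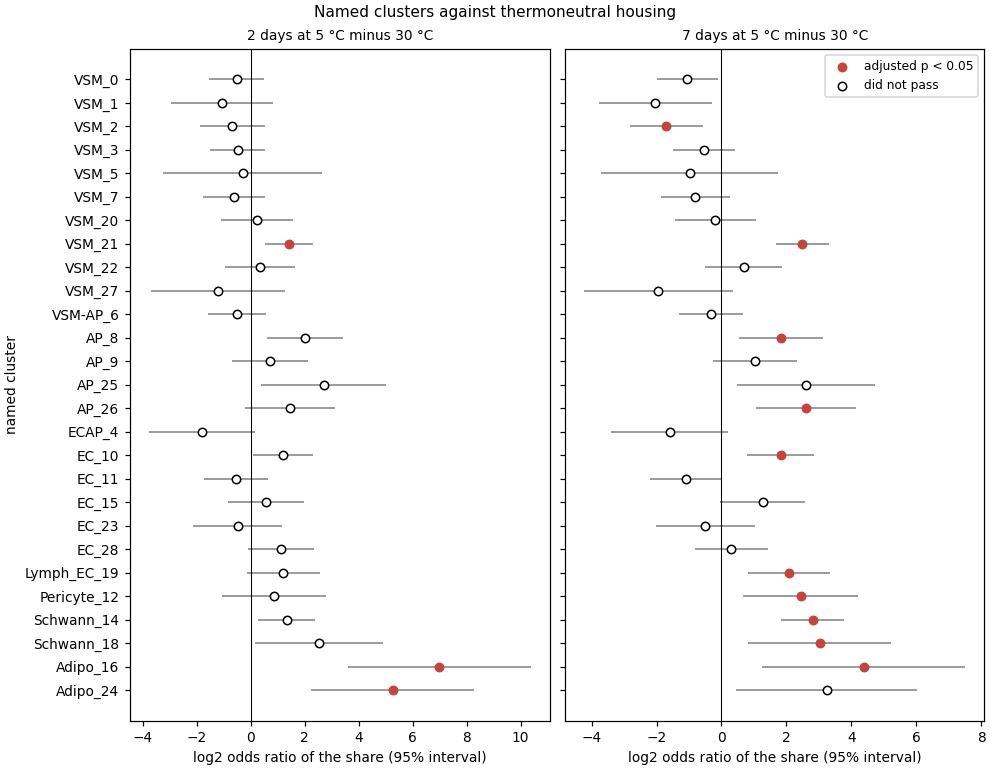
Log2 odds ratio of the share of named cells, with 95% interval from limma, for the 27 tested named clusters in 2-day cold (left) and 7-day cold (right) minus thermoneutral housing; filled points passed an adjusted p of 0.05 and open points did not. Of the 10 VSM clusters in 7-day cold, VSM_21 lies at 2.49 and VSM_2 at -1.70.

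The cold groups were also compared with room temperature. In 2-day cold, Adipo cells were 12.7% ± 10.7 (SD, n = 3) of named cells against 3.15% ± 5.93 (n = 4), AP cells 14.8% ± 4.91 against 6.69% ± 2.79 and VSM cells 38.8% ± 5.49 against 54.3% ± 11, and none of these passed. Among all cells, cluster 23 rose to 3.49% ± 4.03 (SD, n = 4) from 0.0105% ± 0.0210, cluster 36 to 1.54% ± 0.728 from 0.120% ± 0.145, and the Adipo-dominated cluster 11 to 7.34% ± 12.2 from 0.191% ± 0.349. In limma the log2 odds ratios were 6.85 ± 1.10 for cluster 23 (adjusted p = 0.000625), 4.05 ± 0.73 for cluster 36 (adjusted p = 0.00125) and 5.53 ± 1.50 for cluster 11 (adjusted p = 0.0370), with 9.45 and 1.60 for cluster 11 within the pairs of replicate numbers. All 3 calls were higher, with 5 without 2-day replicate 3 and 0 among cells at or above the median UMI count (clusters 23 and 36 not tested there), and with centred log ratios 3 were higher and 1 lower. Over named clusters and classes limma called 0, with 3 and 2 at an unadjusted p below 0.05, and edgeR called 0 in both. These counts were 1 named cluster without room-temperature replicate 2, 2 named clusters and 1 class without room-temperature replicate 4, and 1 class without 2-day replicate 3. With libraries of 3000 cells or more alone, the Adipo class passed at 5.74 ± 1.17 (limma, adjusted p = 0.00276), as did Adipo_16. Cluster 11 lost its call in 15 of 30 settings, among them without 2-day replicate 1, 2 or 4, without room-temperature replicate 1, 2 or 3, without thermoneutral replicate 1 or 4 and without 7-day replicate 2.

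In 7-day cold against room temperature, VSM cells fell to 30.5% ± 6.92 (SD, n = 4) of named cells from 54.3% ± 11 (n = 4). Schwann cells rose to 12.3% ± 1.24 from 4.75% ± 2.91, AP cells to 16.1% ± 3.99 from 6.69% ± 2.79 and Lymph_EC cells to 3.5% ± 1.49 from 1.25% ± 1.06. Schwann_14 rose to 9.07% ± 2.54 from 1.75% ± 0.624 and VSM_21 to 3.62% ± 1.32 from 0.941% ± 0.300; they were the 2 of 27 named clusters that passed. With replicates 1 and 2 against 3 and 4 as a covariate 8 passed, the added ones being AP_26, Lymph_EC_19 and Pericyte_12 as higher and VSM_0, VSM_1 and VSM_27 as lower. The Pericyte class passed too (1.97 ± 0.57, limma, adjusted p = 0.0190; 0.0552 without the covariate). Among cells under 20% mitochondrial UMIs 6 named clusters passed, the added ones being AP_26 and Lymph_EC_19 as higher and VSM-AP_6 and VSM_0 as lower. In limma the log2 odds ratios were 2.47 ± 0.46 for Schwann_14 (adjusted p = 0.00199) and 1.91 ± 0.38 for VSM_21 (adjusted p = 0.00238). The 4 classes had adjusted p-values of 0.0442, with -1.46 ± 0.48 for VSM, 1.74 ± 0.63 for Schwann, 1.49 ± 0.57 for AP and 1.72 ± 0.58 for Lymph_EC. Within replicates 1 and 2 and within 3 and 4, VSM gave -2.03 and -0.89, Schwann 2.56 and 0.92, Schwann_14 2.69 and 2.26, and VSM_21 2.53 and 1.29. Without cells of 20% or more mitochondrial UMIs, VSM-AP moved from -0.82 ± 0.46 to -2.14 ± 0.52 and passed (limma, adjusted p = 0.00441), and the Pericyte class passed as higher. The class calls lay close to the threshold. Of the 4, 3 were higher and 1 lower, while with TMM scaling or centred log ratios 0 were higher and 2 lower, and edgeR without scaling called 0. No class passed in limma among cells at or above the median UMI count, with libraries of 3000 cells or more, or with VSM left out of the denominator. Leaving out thermoneutral replicate 3, room-temperature replicate 1 or 2, 2-day replicate 2, or 7-day replicate 1, 2 or 3 gave 0 class calls, thermoneutral replicate 2 gave 1 and 7-day replicate 4 gave 2. The count of 2 named clusters was 4 without room-temperature replicate 3 or 4 and 6 without 7-day replicate 4. Over the 55 clusters of all cells limma and edgeR called 0, with 10 at an unadjusted p below 0.05 in limma. Among cells under 20% mitochondrial UMIs it called 2 (clusters 4 and 24, lower).

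The exposures to cold were compared directly. Cluster 23 fell to 0.0339% ± 0.0239 (SD, n = 4) of all cells in 7-day cold from 3.49% ± 4.03 (n = 4) in 2-day cold. Adipo cells were 1.95% ± 1.09 (n = 4) of named cells against 12.7% ± 10.7 (n = 3), Pericyte cells 10.1% ± 8.77 against 2.67% ± 1.63 and Schwann cells 12.3% ± 1.24 against 7.11% ± 5.44, none of which passed. The log2 odds ratio of cluster 23 in limma was -5.34 ± 1.10 (adjusted p = 0.00932), with -3.39 and -7.28 within the pairs of replicate numbers. It was the 1 call of 55, a count that was 2 without room-temperature replicate 4, 4 without 2-day replicate 3 and 0 without 2-day replicate 4. Among cells at or above the median UMI count it was 8, without cluster 23, which had too few cells to be tested there. These were clusters 0, 1, 2 and 21 as higher and 11, 22, 26 and 45 as lower. The count was 2 among cells under 20% mitochondrial UMIs, 3 with libraries of 3000 cells or more and 0 with one UMI floor. Over the named clusters and the classes limma called 0, with 2 and 0 at an unadjusted p below 0.05, and edgeR called 0 in both, or 1 class with TMM scaling. Over all 4 conditions, limma's test passed the classes Adipo, Schwann, VSM, Lymph_EC and AP (adjusted p from 0.0105 to 0.0346). It also passed the named clusters VSM_21, Schwann_14 and Adipo_16 (0.00116, 0.00116 and 0.0312) and clusters 23, 36, 11 and 45 of all cells (0.000856, 0.000856, 0.0176 and 0.0315). An exact permutation test of each share, with the same adjustment, called 0 clusters or classes in all 6 comparisons. Its smallest p is 0.0286, so a call needs most of a family at that p together, and the 0 says little against the limma calls.

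Phase calls, made by the authors from S and G2M gene scores, were compared as calls and are not read as cycling, since depth and free RNA enter them. Cells called S or G2M made up 49.6% ± 10.7 (SD, n = 4) of a library at thermoneutrality, 55.3% ± 13.7 at room temperature, 53.4% ± 19.6 in 2-day cold and 55.1% ± 8.33 in 7-day cold, with exact permutation p-values of 0.40 or more in the 6 comparisons. Standardised over clusters, the difference was 9.11 points for room temperature minus thermoneutrality, -3.84 for 2-day cold and -11.2 for 7-day cold minus room temperature, each at the smallest exact p of 0.0286 and none past the threshold once adjusted over the 6 comparisons (adjusted p = 0.0571). It then turned from 5.50 to -2.12 for 7-day cold minus thermoneutrality and from 1.72 to -7.38 for 7-day minus 2-day cold (exact p = 0.229 and 0.0571). Within 11 clusters with enough cells in every library, the share was higher at room temperature than at thermoneutrality in 5, all without named cells: in cluster 0 it was 77.1% ± 2.58 against 63.9% ± 3.84, in cluster 15 91.7% ± 5.31 against 75.2% ± 4.80, in cluster 2 74.3% ± 2.46 against 64.7% ± 4.18, in cluster 5 75.1% ± 4.81 against 61.4% ± 3.52 and in cluster 7 85.9% ± 4.64 against 76.2% ± 5.06. It was lower in 7-day cold than at room temperature in 7, these 5 and clusters 21 and 4; cluster 4, in which 98.4% of named cells were VSM, was at 1.50% ± 1.96 against 10.1% ± 4.63. It was lower in 7-day than in 2-day cold in 4, with the EC-dominated cluster 18 at 21.9% ± 5.74 against 47.2% ± 14.3, besides clusters 0, 2 and 5. The limma log2 odds ratios of cluster 0 were 0.92 ± 0.20 (adjusted p = 0.00408) for room temperature minus thermoneutrality, -1.10 ± 0.20 (adjusted p = 0.000799) for 7-day cold minus room temperature and -0.62 ± 0.20 (adjusted p = 0.0222) for 7-day minus 2-day cold. Between 2-day cold and thermoneutrality, 7-day cold and thermoneutrality, and 2-day cold and room temperature limma called 0, with 5, 1 and 2 at an unadjusted p below 0.05; no other tool was run on these shares. In 2-day cold against thermoneutrality the count was 3 without room-temperature replicate 4 and 4 without 2-day replicate 1, and in 7-day cold against thermoneutrality 1 without 7-day replicate 3. With the covariate of replicate numbers, cluster 4 passed as lower in 7-day cold against thermoneutrality and against 2-day cold, and in 2-day cold against room temperature. Cluster 18 then passed as lower in 7-day cold against room temperature. With cells of middle depth alone, cluster 5 passed as higher in 2-day cold and cluster 13 at room temperature, both against thermoneutrality. With such cells, the calls of clusters 4 and 7 in 7-day cold against room temperature and of clusters 0 and 18 in 7-day against 2-day cold were lost. Calls were also lost without room-temperature replicate 1 or 2 (cluster 7 against thermoneutrality, clusters 7 and 21 in 7-day cold). The same held without room-temperature replicate 3 or 7-day replicate 1, 2 or 3 (cluster 21 in 7-day cold, with cluster 7 for the last 3) and without thermoneutral replicate 1 (cluster 7 at room temperature). It also held without thermoneutral replicate 2 or 3 or 2-day replicate 4 (cluster 7 in 7-day cold), and without 2-day replicate 2 or 3 or 7-day replicate 2 or 4 (cluster 0 in 7-day against 2-day cold).

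With the phase calls of the named cells, which were scored separately, 2 clusters had enough cells. VSM_0 was called S or G2M in 34.2% ± 12.6 (SD, n = 4) of cells in 7-day cold, below 63.5% ± 5.62 at thermoneutrality, 65.3% ± 4.41 at room temperature and 52.4% ± 8.40 (n = 3) in 2-day cold (limma, adjusted p = 0.000236, 0.000127 and 0.0191). VSM-AP_6 was at 44.6% ± 5.60 (n = 3) in 2-day cold, below 58.2% ± 4.27 at thermoneutrality and 56.3% ± 1.53 at room temperature (limma, adjusted p = 0.0129 and 0.0330). With cells of middle depth alone, the calls of VSM_0 in 7-day cold against thermoneutrality and against 2-day cold, and of VSM-AP_6 in 2-day cold against thermoneutrality, were lost. Without 2-day replicate 2 both VSM-AP_6 calls were lost, without room-temperature replicate 2, 3 or 4 the one against room temperature, and without 2-day replicate 4 that of VSM_0 against 2-day cold. With the covariate of replicate numbers VSM_0 passed as lower in 2-day cold against both thermoneutrality and room temperature, the last also with cells of middle depth. Each count of 1 was 2 in 2-day cold against thermoneutrality without 7-day replicate 1, in 2-day cold against room temperature without 2-day replicate 4 or 7-day replicate 1 or 4, and in 7-day against 2-day cold without 2-day replicate 3 or 7-day replicate 3. Between room temperature and thermoneutrality limma called 0 of the 2, with 0 at an unadjusted p below 0.05.

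**Figure D5:**
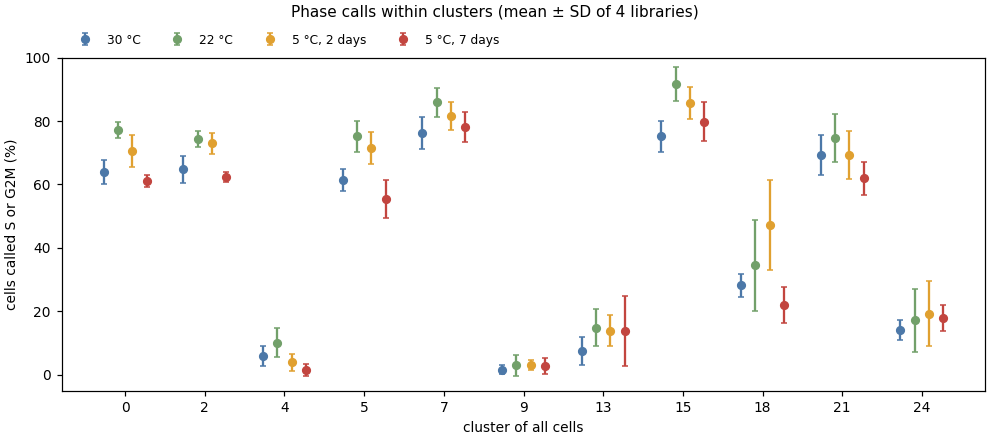
Share of cells called S or G2M (percent) within the 11 clusters of all cells that held at least 20 cells in every library, as mean ± SD of 4 libraries per housing condition. In clusters 0, 2, 5, 7 and 15 the room-temperature mean lies above the thermoneutral and the 7-day means.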

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

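Of the tests below, those of one library, cell recovery, depth and the library size limit behind the Adipo shares were chosen after the result was seen; the test of mitochondrial share was written down first. In 24 of 104 groups of 4 libraries, 1 library lay far from the others by Dixon's ratio of its gap to the group's range, at the 95% level. Chance gives about 1 in 20 groups, and many of these shares rest on few cells. Replicate 1 of 2-day cold had a median of 9819 UMIs (others 2486 to 3189), a median mitochondrial share of 29.1% (others 2.47% to 3.70%) and 25.6% of its cells in cluster 11 (others 0.195% to 1.83%). Room-temperature replicate 4 had a median mitochondrial share of 6.01%, 12% of named cells in the Adipo class, 9.80% in Adipo_16 and 2.24% in Adipo_24, and 0.713% of all cells in cluster 11, 0.0419% in cluster 23 and 0.336% in cluster 36. Thermoneutral replicate 1 held 4.31% Schwann, 1.63% Schwann_18, 4.71% AP_8 and 0.107% Adipo_24 among named cells, and 0.00999% of all cells in cluster 11 and in cluster 45. Thermoneutral replicate 2 held 0.187% Adipo_16, and thermoneutral replicate 3 held 2.53% EC_10. Among the libraries of 7-day cold, replicate 2 held 10.7% AP_8, replicate 3 held 40.8% VSM and 1.8% Adipo_24 and 0.233% of all cells in cluster 45, and replicate 4 held 16.6% ECAP and 0.611% of all cells in cluster 11. All of these were the highest of their group.

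The Adipo clusters were higher in 2-day cold than at thermoneutrality. With the log2 median UMI count of the library as a covariate the Adipo class was at 6.33 ± 1.60 (log2 odds ratio ± SE, 7.02 ± 1.48 without it). Cell composition enters that median, since Adipo cells had a median of 31347 UMIs and all cells one of 3385. The covariate therefore cannot decide on depth as a cause. The library size limit was argued against as the whole cause by 6.18 ± 2.23 without the libraries of 10000 cells or more, but with fewer libraries the spread was wider and the call ended (limma, adjusted p = 0.0768). One library as the whole source was argued against, since the class, in which replicate 1 of 2-day cold has no cells, kept its call without any one library, at 6.19 ± 1.67 or more. Among all cells, 3 of the 4 libraries of 2-day cold lay above every thermoneutral library in their share of Adipo-dominated clusters, and that replicate held 78.7% of the cells in these clusters. They include cluster 20, in which 60.9% of the named cells were Adipo. Thermoneutral replicate 4, the highest of its group at 1.10%, had 0 cells named Adipo. A high mitochondrial share cannot be told apart: without cells at 20% or more the estimate went from 7.02 ± 1.48 to 3.70 ± 1.50 and the call ended (limma, adjusted p = 0.0796), and although this stays above 0 by 2 SE, as the test asked, the limit itself removed 84.7% of the Adipo cells and left 0 in one cold library, so that bound was not applied (decided once the cells left were counted and before the estimate was seen). Recovery of fragile cells is consistent with 1 library of 2-day cold lying inside the range of the other conditions, and since fat cells were taken off during preparation it may account for part of the difference; a rise of adipocytes with cold stays open and untested.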

How the results depend on the processing

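Alternatives chosen only after seeing the data were the common UMI floor, the limit of 20% mitochondrial UMIs, the set of libraries with 3000 cells or more, the classes and their denominators (all cells, VSM or Adipo left out) and, for phase calls within clusters, replicates 1 and 2 against 3 and 4 as a covariate, called the pair covariate below. In no setting did a called cluster or class change direction. Below, comparisons are written as the first condition minus the other, with TN for thermoneutrality, RT for room temperature and cold2 and cold7 for 2 and 7 days of cold, and "the cause was not tested" holds for every change unless one is given. The exact permutation test called 0 in each family and comparison, against 5, 3 and 1 clusters of all cells (cold2-TN, cold2-RT, cold7-cold2), 3, 10 and 2 named clusters (cold2-TN, cold7-TN, cold7-RT) and 1, 6 and 4 classes in the same. Its smallest p of 0.0286 is set by the number of libraries, so that a call needs most of a family at that p together. Clusters of all cells, cold2-TN: there were 3 on the arcsine scale, 2 with a mean of 50 cells, 3 with cells at or above the median UMI count, 2 under 20% mitochondrial UMIs and 3 at clustering resolution 0.4. In cold7-TN there were 3 under 20% mitochondrial UMIs and 1 with the 2 groups alone. The range over left-out libraries was 0 to 1 (1 without RT replicate 4). In cold2-RT there were 0 with cells at or above the median UMI count. Leaving out 1 library gave 2 to 5 (5 without cold2 replicate 3). In cold7-RT there were 2 under 20% mitochondrial UMIs. In cold7-cold2 there were 3 with TMM, 8 with cells at or above the median UMI count, 0 with the UMI floor, 2 under 20% mitochondrial UMIs, 3 with libraries of 3000 cells or more and 0 at resolution 0.4. With single libraries left out the count was 0 to 4 (0 without cold2 replicate 4, 4 without cold2 replicate 3, 2 without RT replicate 4). Named clusters, RT-TN: there was 1 with no filter on rare clusters. In cold2-TN there was 1 on the arcsine scale, 1 with centred log ratios, 5 with no filter, 0 with a mean of 50 cells, 0 under 20% mitochondrial UMIs (where fewer Adipo cells were left) and 1 at resolution 0.4. The range over left-out libraries was 0 to 7 (0 without TN replicate 4 or cold2 replicate 2 or 4, 1 without TN replicate 3, 7 without TN replicate 1). In cold7-TN there were 6 with a mean of 50 cells (fewer clusters tested) and 17 with the pair covariate. Leaving out 1 library gave 4 to 14 (4 and 5 without TN replicates 4 and 3, 14 without TN replicate 1 or 2). In cold2-RT there was 1 with libraries of 3000 cells or more. With single libraries left out the count was 0 to 2 (1 and 2 without RT replicates 2 and 4). In cold7-RT there was 1 with a mean of 50 cells, 1 with cells at or above the median UMI count, 1 with the UMI floor, 6 under 20% mitochondrial UMIs, 4 with the 2 groups alone, 8 with the pair covariate and 5 at resolution 0.4. The range over left-out libraries was 2 to 6 (4 without RT replicate 3 or 4, 6 without cold7 replicate 4). In cold7-cold2 there was 1 on the arcsine scale. Classes, cold2-TN: there were 4 with centred log ratios, 2 under 20% mitochondrial UMIs and 2 with Adipo left out. Leaving out 1 library gave 1 to 3 (3 without TN replicate 1, 2 without TN replicate 2, RT replicate 1 or cold2 replicate 4). In cold7-TN there were 3 with TMM, 0 with all cells as denominator and 3 with VSM left out. For classes, leaving out the most abundant is the same fit as leaving out VSM, and it is given once. In cold2-RT there was 1 with libraries of 3000 cells or more. With single libraries left out the count was 0 to 1 (1 without RT replicate 4 or cold2 replicate 3). In cold7-RT there were 2 with TMM, 2 with centred log ratios and 0 with edgeR, with a mean of 50 cells, with cells at or above the median UMI count, with libraries of 3000 cells or more, with all cells as denominator (also with the pair covariate) and with VSM left out. The range over left-out libraries was 0 to 5 (0 without TN replicate 3, RT replicate 1 or 2, cold2 replicate 2 or cold7 replicate 1, 2 or 3, 1 without TN replicate 2, 2 without cold7 replicate 4). In cold7-cold2 there was 1 with TMM. Phase calls within clusters of all cells, cold2-TN: there was 1 with cells of middle depth. Leaving out 1 library gave 0 to 4 (3 without RT replicate 4, 4 without cold2 replicate 1). In cold7-TN there was 1 with the pair covariate. With single libraries left out the count was 0 to 1 (1 without cold7 replicate 3). In cold2-RT there was 1 with the pair covariate. In cold7-cold2 there were 2 with cells of middle depth. Phase calls within named clusters, cold2-TN: there were 2 with the pair covariate and 0 with cells of middle depth. The range over left-out libraries was 0 to 2 (0 without cold2 replicate 2, 2 without cold7 replicate 1). In cold7-TN there were 0 with cells of middle depth. In cold2-RT there were 2 with the pair covariate and 2 with cells of middle depth. Leaving out 1 library gave 0 to 2 (0 without RT replicate 2, 3 or 4 or cold2 replicate 2, 2 without cold2 replicate 4 or cold7 replicate 1 or 4). In cold7-cold2 there were 0 with cells of middle depth. With single libraries left out the count was 0 to 2 (0 without cold2 replicate 4, 2 without cold2 replicate 3 or cold7 replicate 3). Cells called S or G2M per library, in percentage points, standardised over clusters: RT-TN 9.11, cold2-RT -3.84 and cold7-RT -11.2 had an exact p of 0.0286 each and an adjusted p of 0.0571, which did not pass, while cold7-TN turned to -2.12 and cold7-cold2 to -7.38. The cold7-cold2 difference was -5.08 with cells of middle depth, and the mean S score differed by -0.000923 and the mean G2M score by -0.0111 there and by -0.0105 in cold7-TN. With a library left out these shares ran from -1.24 to 13.4 (cold2-TN), -7.46 to 7.60 (cold2-RT), -5.74 to 4.22 (cold7-RT) and -7.86 to 6.74 (cold7-cold2). Depth, as the mean of cluster medians: the UMI difference turned to -286 (cold2-TN), 856 (cold7-TN), -390 (cold2-RT), 752 (cold7-RT) and 1142 (cold7-cold2), genes to -41.3 (RT-TN), 149 (cold7-TN) and 191 (cold7-RT), and the mitochondrial share to -0.591 (cold2-RT), 0.253 (cold7-RT) and 0.844 (cold7-cold2) points. With a library left out, cells per library ran from -5622.5 to -3257 (cold7-cold2, where the exact p was 0.0857 without any one cold2 replicate), 3115 to 5653.5 (cold2-RT, exact p 0.0286 without RT replicate 3) and -1451 to 1147.5 (cold7-RT). Median UMIs ran from -756 to 1025.5 (RT-TN), -1280 to 1164 (cold2-TN), -814 to 0.833 (cold7-TN), -1535 to 1242 (cold2-RT), -1411 to 371 (cold7-RT) and -1550 to 894.5 (cold7-cold2). Median genes ran from -226 to 258 (RT-TN), -146 to 114.5 (cold7-TN), -387 to 96.8 (cold2-RT), -276 to 209 (cold7-RT) and -16.7 to 275 (cold7-cold2). The mitochondrial share ran from -0.304 to 0.692 (RT-TN), -0.339 to 8.55 (cold2-TN), -0.727 to 8.16 (cold2-RT), -0.299 to 0.688 (cold7-RT) and -8.17 to 0.722 (cold7-cold2) points. Among single calls, 151 values in other settings and 115 with a library left out were no longer past the threshold, against 528 and 885 that were or that moved by less than the spread, and 15 mean shares moved by more than 1 SD. The replicate numbers were not taken to pair the libraries, since not every same-number pair correlated above 0.1 in the deviations from the group means: 19 of 24 did for all cells, 12 of 21 for named clusters and 10 of 21 for classes. For all cells, the median correlation of same-number libraries (0.262) was no higher than that of libraries with the other number of replicates 1 and 2 or 3 and 4 (0.284), and across these it was -0.280. For named clusters these were 0.220, 0.162 and -0.195, and for classes 0.0814, 0.107 and -0.117. As a hint from the data, 11 of 16, 7 of 15 and 2 of 15 libraries correlated best with their own number. The replicate block gave 1 named cluster (Adipo_16) in cold2-TN and 8 in cold7-RT, for phase calls 2, 1 and 1 within clusters of all cells (cold2-TN, cold7-TN, cold2-RT) and 2 and 2 within named clusters (cold2-TN, cold2-RT), and left the cell difference of cold7-cold2 at -4506, where sign flips of 4 pairs cannot reach the threshold. Comparison of pseudotime was not run, since no pseudotime was analysed here, and neither was another resolution for the classes. Few cells per library limit rare clusters: the added 0.5 cells set the size of ratios against shares near 0.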

Other observations

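Of the tests below, those of depth, of unnamed cells, of replicate numbers and of a smaller VSM share for AP, Lymph_EC and Pericyte were chosen after the result was seen, as were those of one library, of replicate numbers and of depth as a covariate for clusters 23 and 36, and the leaving out of libraries of 10000 cells or more. The UMI floor was chosen after the data were seen. The classes themselves were formed after the names had been seen, and for phase calls the counts, but not the splits, had been seen.

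VSM-AP_6 had a median mitochondrial share of 25.2%, with 66.5% of its cells at 20% or more (Adipo class 33.5% and 84.7%), while ECAP_4 was at 1.47% and AP_8 at 1.67%. The median UMI count was 48040 in Adipo_24 and 27580.5 in Adipo_16, against 2642 in Schwann_18 and 3120 in VSM_21. Cluster 20 of all cells, in which 60.9% of the named cells were Adipo, had a median mitochondrial share of 48.9%, and 78% of its cells came from replicate 1 of 2-day cold. EC_32 held 0.434% ± 0.0945 (SD, n = 3) of named cells in 2-day cold and 0.412% ± 0.131 (n = 4) at room temperature, against 0.0468% ± 0.0936 at thermoneutrality and 0.118% ± 0.0923 in 7-day cold. It held 62 cells in all and was left out of the main tests. With no filter on rare clusters, where EC_32 was the cluster added, limma called 1 named cluster at room temperature (0 with the filter). In 2-day cold it called 5 (3 with the filter, AP_8 among the added), both against thermoneutrality.

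VSM cells were lower, and 5 other named classes higher, in 7-day cold than at thermoneutrality. A smaller VSM share alone was argued against for Adipo and Schwann, the 2 of these classes that stayed past the threshold with VSM left out of the denominator (ECAP then passed as lower), while for AP, Lymph_EC and Pericyte it cannot be told apart from a rise of their own, since their estimates then ended at 1.68 ± 0.79 or lower and none was called. With the log2 median UMI count of the library as a covariate VSM was at -1.77 ± 0.47. VSM cells had a median of 8561.5 UMIs and all cells one of 3385, so the VSM share itself enters the covariate. This cannot decide on depth as a cause. The difference between replicate numbers was argued against as the whole cause by -1.32 (SE 0.45) within replicates 1 and 2, the smaller of the pair. As a share of all cells VSM gave -1.94 ± 0.76, against -1.72 ± 0.48 among named cells. The number of unnamed cells enters only the first of these, so the comparison cannot decide on it as a cause. Clusters of mostly named cells held 20.9% of cells in 7-day cold and 32.7% at thermoneutrality (exact permutation p = 0.229). Among all cells the spread of VSM was wider and the call ended (limma, adjusted p = 0.0595), as it did among named cells without the libraries of 10000 cells or more (-1.56 ± 0.62, limma, adjusted p = 0.0537). A loss of VSM cells with 7 days of cold and a change in how well these cells were recovered both stay open and were not tested.

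Clusters 23 and 36, mostly cells called S and without names, were higher in 2-day cold. One library as the whole source was argued against, since all 4 libraries of 2-day cold exceeded every library of the other conditions in the summed share (0.970% to 10.5%, others up to 0.543%). It follows that this held within both (2 of 2) pairs of replicate numbers, so their difference was not the whole cause, but that is no separate test. The size did differ by replicate number: 0.970% and 1.97% in 2-day replicates 1 and 2, against 10.5% and 6.67% in 3 and 4. Replicate 3 of 2-day cold held 63.0% of the cells of cluster 23. Against thermoneutrality, the library size limit was argued against as the whole cause by 5.60 ± 1.28 with one UMI floor. With the log2 median UMI count of the library as a covariate the estimate was 5.07 ± 0.72, each value being the lower of the cluster estimates. Cell composition enters that median, so the covariate cannot decide on the depth of the libraries. Of the 1377 and 670 cells of clusters 23 and 36, 59 and 143 lay at or above the median UMI count, too few to be tested. The depth of the single cells was therefore not tested. With the floor, cluster 23 in 7-day against 2-day cold went from -5.34 ± 1.10 to -4.61 ± 1.28, smaller and with a wider spread, and the call ended (limma, adjusted p = 0.0962), and without the libraries of 10000 cells or more so did that of cluster 36 against room temperature (4.05 ± 0.73 to 3.71 ± 0.94, adjusted p = 0.0735). No gene values were used to tell what these cells are, so a cell state of early cold exposure, doublets and free RNA all stay open and were not tested.

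For each comparison, the libraries were also split in every other way into groups of the same sizes, 35 splits each. These counts alone do not exclude chance, since the splits mix replicates 1 and 2 with 3 and 4. In several comparisons the real split alone gave as many calls, 1 of 35 and the smallest possible share. These were the clusters of all cells in 2-day cold against thermoneutrality (5 calls, highest other 2) and the named clusters in 7-day cold against thermoneutrality (10, highest other 7) and against room temperature (2, highest other 1). The same holds for the classes in the same comparisons (6, highest other 2, and 4, highest other 1). The real split also stood alone for phase calls within clusters of all cells at room temperature against thermoneutrality (5, highest other 0), in 7-day cold against room temperature (7, highest other 2) and in 7-day against 2-day cold (4, highest other 2). Other splits gave as many calls for clusters of all cells in 2-day cold against room temperature (3 splits gave as many, real 3, highest other 5) and in 7-day against 2-day cold (3 splits, real 1, highest other 1), so chance cannot be excluded there either. This also applies to the named clusters in 2-day cold against thermoneutrality (3 splits, real 3, highest other 4) and to the classes there (5 splits, real 1, highest other 3). For phase calls within named clusters the count decides nothing, since it runs over 2 clusters alone. In 2-day and 7-day cold against thermoneutrality 2 and 6 splits gave as many (real 1, highest other 1). Against room temperature 1 did in 2-day cold (real 1, highest other 0) and 4 in 7-day cold (real 1, highest other 1), and in 7-day against 2-day cold 8 did (real 1, highest other 2). Where the real count was 0, all 35 splits gave as many. The highest other counts were 3, 3 and 2 for all clusters, named clusters and classes at room temperature against thermoneutrality. They were 0 and 4 for all clusters in 7-day cold against thermoneutrality and room temperature, 2 and 2 for named clusters and classes in 2-day cold against room temperature, and 2 and 1 for these in 7-day against 2-day cold. For phase calls with a real count of 0 they were 1, 1 and 2 within clusters of all cells (2-day and 7-day cold against thermoneutrality, 2-day cold against room temperature) and 0 within named clusters (room temperature against thermoneutrality). The split of replicates 1 and 2 against 3 and 4, across room temperature and thermoneutrality, gave 3 calls in all clusters and 3 in named clusters. Across the cold groups it gave 2 named clusters and 1 class, more than the real comparisons. With these pairs of replicate numbers as a covariate the real comparisons still gave 0 calls. This points to a structure of the libraries by replicate number, which the 35 splits do not hold fixed. In a count chosen after this was seen, 18 of the splits kept as many of replicates 1 and 2 in each group as the real one, too few for a share under 0.05. With the covariate fitted, the real and the highest other count were 17 and 0 for named clusters in 7-day cold against thermoneutrality and 8 and 1 against room temperature, and 6 and 0, and 5 and 1, for the classes there. For clusters of all cells they were 5 and 2 in 2-day cold against thermoneutrality, 3 and 5 against room temperature and 1 and 1 in 7-day against 2-day cold. In 2-day cold against thermoneutrality they were 3 and 6 for named clusters and 1 and 3 for classes. For phase calls within clusters of all cells they were 5 and 1 at room temperature against thermoneutrality, 8 and 3 in 7-day cold against room temperature and 5 and 1 in 7-day against 2-day cold.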
